A study of Mus musculus with 4 samples.

How the data were processed

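Alveolar type 1 (AT1) cells are the thin, flat cells that cover most of the gas-exchange surface of the lung. The 4 RNA-seq libraries came from AT1 cells sorted from mice on a mixed background at postnatal day 3 or 4. Per the labels, every animal carried the Cre recombinase under the Scnn1a gene, together with either a Cre-dependent Sox2 transgene or a Cre-dependent membrane reporter, each inserted at the Rosa locus. The libraries of the first kind are called here labelled Sox2 and those of the second kind labelled control, with 2 libraries each. Per the labels' protocols, the lung edge was digested with collagenase, DNase and trypsin, red blood cells were lysed, dead cells were excluded with a dye during sorting, and poly-A RNA was made into libraries for a HiSeq2000. Groups were taken from the sample titles. No label says that the libraries of a group came from separate animals. Xist and Y-linked genes place the 2 libraries labelled Sox2 in different animals, and nothing shows it for those labelled control, so p-values measure only the spread between these libraries.

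The deposited values are FPKM (fragments per transcript length and sequencing depth) per gene, with a lower and an upper bound per value, as the authors' tables name them in their headers. Per the submitters' processing notes, TopHat2, Bowtie2, Cufflinks and Cuffdiff were used with the mouse build mm10; their versions, the gene annotation and the strand setting are not given in the sources used here. Read counts are not part of the tables used here, so absolute depth is unknown. The width of the bounds served as a guide to relative depth, on the untested assumption that depth sets it. Setting the depth of labelled Sox2 replicate 1 to 1, the value was 0.462 for labelled Sox2 replicate 2, 0.821 for labelled control replicate 1 and 0.570 for labelled control replicate 2. The share of low values that came out as whole implied fragments, within 0.1 of a whole number, was 63.5% to 67.1% per library, so counts were not rebuilt. In labelled control replicate 2, small RNA genes (symbols starting Mir or Snor) held 367470 of a summed 721290 FPKM, against 16835 of 292470 in labelled Sox2 replicate 2. A further table held 2 columns of group values that no label ties to a group. It was not used, and the comparison with the authors' Cuffdiff result planned before the data were examined was therefore not made.

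Each table listed 24490 entries. They were joined by gene symbol and position, and entries of the same symbol were added, which concerned 267 genes. Rn45s was left out because its value was marked as failed in 3 libraries, which left 23990 genes. Genes with a mean of at least 1 FPKM over the 4 libraries were tested, 12040 in all. Testing used log2(FPKM + 1) in limma 3.58.1 under R 4.3.3, with a linear model per gene and moderated variances that follow a trend with expression (lmFit, then eBayes with trend). Tests were two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Log2 differences are coded as labelled Sox2 minus labelled control on the log2(FPKM + 1) scale, which understates the change of low genes. The model left 2 residual degrees of freedom per gene before moderation. With 2 against 2 libraries, an exact permutation test of a single gene cannot give a p-value below 0.333, so no such test is reported.

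Before the data were examined, 32 gene lists were fixed: lung epithelial cell types, pathways, other cell types that a sort of lung-edge tissue can hold, stress genes and reference genes. Each list was set against all other tested genes with limma's camera test at its preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation served as an alternative, as did limma's fry test, which asks whether a list's genes changed on balance and does not set them against other genes. The genes named in the text followed a rule fixed at the same time. It takes Sox2, then the 8 genes with the largest difference in each direction among those past the threshold whose groups do not overlap, leaving out RIKEN, Gm and small RNA symbols. From each list it takes up to 4 members past the threshold with the largest absolute difference, or the 2 most abundant where none passed. The rule selects 104 genes, of which the text prints a part. A further 11 tested genes, namely Ager, Hopx, Sftpc, Scgb1a1, Foxj1, Trp63, Mki67, Scnn1a, Pdpn, Cdkn1a and Cdkn2b, were chosen after their values were seen, as were the untested Krt5 and Krt14 and the microRNA gene Mir684-1.

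The alternatives fixed at the same time were a pseudocount of 0.1, no filter on low values, a filter at a mean of 5 FPKM, median-of-ratios rescaling, quantile normalization, a robust variance model, a variance model without trend, the replicate number as a block, and each library left out in turn. Leaving out genes listed at more than 1 position together with small RNA genes, and leaving out genes shared between lists, were added after seeing the data. The test was run on simulated data built on the same 12040 genes with 200 of them changed. It recovered 2.5% of genes changed by 1 log2 unit, 59.5% at 2 units, 96.3% at 3 units and 99.5% at 4 units, and 5.33% of its calls were false. A simulated list of changed genes was called by camera at an unadjusted p under 0.05 in 20 of 20 runs, and an unchanged list in 0 of 20. Simulated genes were drawn independently of each other, with variances from the fitted model. In the data, the estimated inter-gene correlation within a list reached 0.97. These runs therefore do not show how often a list of correlated genes is called falsely. They also held no difference in scale between libraries and no deviation shared by same-numbered libraries. In the data, 506 genes were called higher and 976 lower. The recovered and false shares of single genes therefore hold for the simulated setting and were not measured for these data. Figures and checks used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Gene positions are those of the tables on mm10, counted from 1. The exon structure of Sox2 came from GENCODE on GRCm38, the assembly that mm10 names.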

Results

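RNA of sorted AT1 cells from newborn mouse lungs was sequenced to ask what the transcription factor Sox2 does to these cells when it is switched on in them. Sox2 is a marker and regulator of the airway epithelium. The libraries labelled Sox2 (n = 2) carry the Sox2 transgene in their genotype label, and the libraries labelled control (n = 2) carry a reporter in its place. Between 11062 and 12096 genes reached 1 FPKM per library. The median half-width of the deposited bounds, for genes of at least 1 FPKM, was 7.96% and 12.4% of the value in the libraries labelled Sox2 and 7.82% and 9.93% in those labelled control. The bounds were wider in replicate 2 of each label. Across the 12040 tested genes, Pearson's r of log2(FPKM + 1) was 0.947 between the libraries labelled Sox2, 0.920 between those labelled control, and 0.791 to 0.850 across labels. These correlations are across genes, which are not independent replicates.

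Sox2 itself went against the labels. Its level was 1.41 and 1.99 FPKM in the libraries labelled Sox2, and 302 and 478 FPKM in the libraries labelled control. The means were 1.70 ± 0.410 (SD, n = 2) and 390 ± 124 (SD, n = 2), a 229-fold difference, and the log2 difference of -7.15 (SE 0.34) had an adjusted p of 2.39e-06 in limma. Sox2 is a gene of 1 exon on chromosome 3, listed at 34650005 to 34652460. The transgene carries the same gene, and the tables do not separate the transgene from the endogenous copy. Every direction given from here on follows the labels as deposited and therefore runs against the level of the gene that the labels name.

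**Figure D1:**
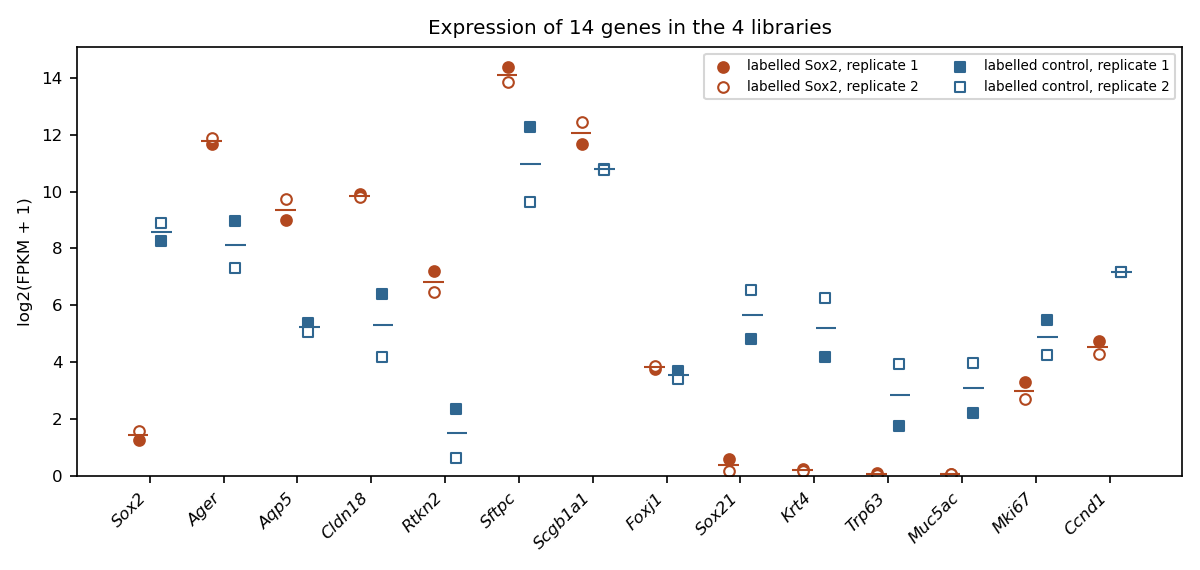
FPKM on a log2(FPKM + 1) scale (vertical axis) for 14 genes in each of the 4 libraries. Circles are the libraries labelled Sox2 and squares those labelled control, filled symbols are replicate 1 and open symbols replicate 2, and bars are means on the log scale. Sox2 lies at 302 and 478 FPKM in the libraries labelled control and at 1.41 and 1.99 FPKM in those labelled Sox2.

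Between the labels, 506 genes were higher and 976 lower in the libraries labelled Sox2, while 10558 did not pass. The naming rule leaves out RIKEN, Gm and small RNA symbols, among them the microRNA gene Mir684-1 (log2 difference -13.8 with no filter on low values). Among the genes it admits, the largest differences upward were those of Rtkn2, a gene enriched in AT1 cells, and the potassium channel subunit Kcne2. Rtkn2 averaged 117 ± 41.8 FPKM (SD, n = 2) in the libraries labelled Sox2 against 2.33 ± 2.51 FPKM (SD, n = 2), and Kcne2 155 against 3.78 FPKM. They were followed by the proteoglycan Spock2 (log2 difference 5.12), the water channel Aqp1 (5.11), the basement membrane collagen Col4a3 (4.82), the sodium channel subunit Scnn1g (4.64), the tight junction protein Cldn18 (4.57) and the guidance cue Sema3a (4.47). Downward, the surface antigen Ly6a stood at 5.51 ± 4.15 FPKM (SD, n = 2) in the libraries labelled Sox2 against 2332 ± 667 FPKM (SD, n = 2). After Sox2 came Dapl1 (-6.17), the phospholipase Pla2g4c (-5.88), the cornified envelope genes Sprr2a2 (-5.76) and Sprr2a1 (-5.72), Sox21 (-5.28), a relative of Sox2, and the aldehyde dehydrogenase Aldh3a1 (-5.19). Sprr2a1 and Sprr2a2 are near-identical copies, so how their fragments were split is uncertain. Adjusted p in limma was at most 0.00248 for these 16 genes, and each kept its call with any 1 library left out. The robust variance model ended the calls of Cldn18, Sprr2a1 and Sprr2a2. The groups did not overlap in 6999 genes, 58.1% of those tested, where chance gives 33.3% for a single gene. Genes are not independent and these values were not rescaled, so the excess is not a test of the labels.

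The median log2 difference of all tested genes was -0.29, and differences below can be read against it. Median-of-ratios rescaling, which moves this median to 0, gave 964 higher and 686 lower genes, a share of 58.4% higher in place of 34.1%, and quantile normalization gave 980 and 827, or 54.2% higher. The counts were 173 and 422 without labelled Sox2 replicate 1, 119 and 115 without labelled Sox2 replicate 2, 837 and 887 without labelled control replicate 1, and 399 and 1312 without labelled control replicate 2. With no filter on low values limma called 0 genes higher and 3 lower, namely Sox2, Pla2g4c and the microRNA gene Mir684-1, while 1251 and 2618 genes had an unadjusted p under 0.05. Of the 96 genes past the threshold that the naming rule selects, 46 passed in all 4 fits with 1 library left out, 84 under both rescalings and 83 under the robust variance model, which ended the calls of Slc34a2, Cxcl15, Lamp3, Chil1, Lama3, Sec14l3, Krt6a, Sema3e, Gsto1 and Hba-a2 as well. It also ended that of Sftpc, which the rule does not select. Folds are ratios of group means and depend on single libraries. Of 103 named genes past the threshold, 63 had a fold that moved by over 1.5 times with 1 library left out, 57 of them without labelled control replicate 1, 42 without labelled control replicate 2, 14 without labelled Sox2 replicate 1 and 10 without labelled Sox2 replicate 2.

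**Figure D2:**
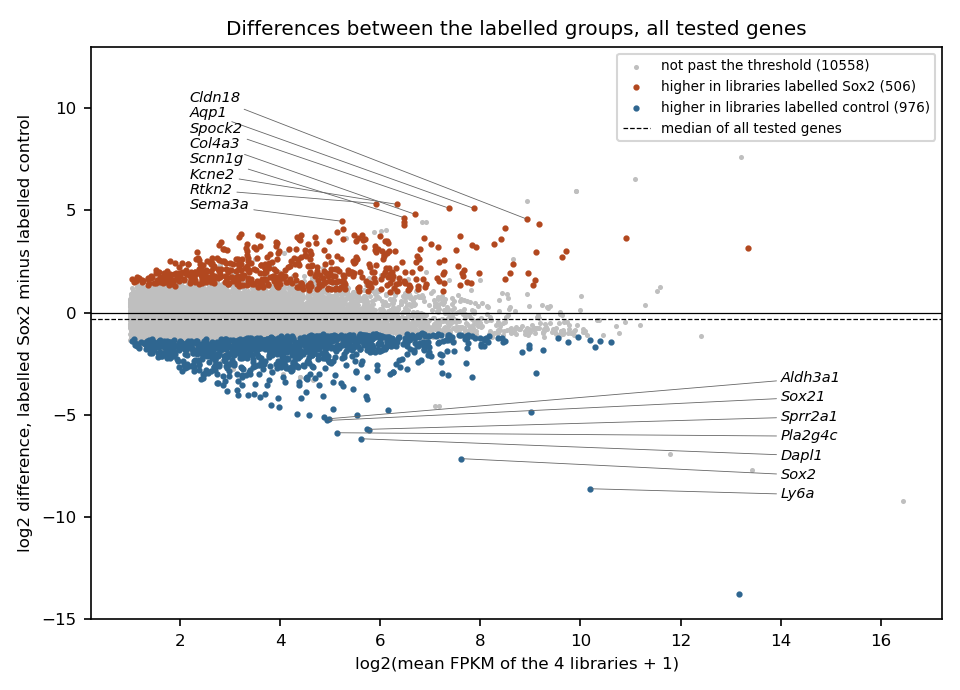
Log2 difference (labelled Sox2 minus labelled control, vertical axis) against log2 of the mean FPKM of the 4 libraries plus 1 (horizontal axis) for the 12040 tested genes. Coloured points passed the threshold, 506 above and 976 below 0, and the dashed line is the median of all tested genes at -0.29. Named points are the genes with the largest differences under the naming rule, which leaves out RIKEN, Gm and small RNA symbols. Sprr2a2 is not named.

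AT1 markers were higher in the libraries labelled Sox2. Of 24 tested markers 18 were higher, none was lower and 6 did not pass, and adjusted over the list alone 20 were higher. Ager, the membrane receptor most used to mark AT1 cells, averaged 3498 ± 337 FPKM (SD, n = 2) in the libraries labelled Sox2 against 326 ± 240 FPKM (SD, n = 2), 10.7-fold more. Rtkn2 (50.1-fold), Spock2 (36.4-fold), Col4a3 (26.8-fold) and Cldn18 (18.5-fold) are members too. Without labelled control replicate 1 the folds were 22.3 for Ager, 210 for Rtkn2, 61.8 for Spock2, 70.3 for Col4a3 and 54.0 for Cldn18, and without labelled control replicate 2 they were 7.06, 28.4, 25.8, 16.5 and 11.2. Hopx, a cofactor found in AT1 cells, had a log2 difference of 0.90 (SE 0.31, limma adjusted p = 0.0833) and passed only under quantile normalization (1.35) and the robust variance model. The list had a median log2 difference of 2.86 and a camera adjusted p of 4.54e-28 in limma, against an adjusted p = 0.476 with an estimated correlation.

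AT2 markers, which belong to the surfactant-making neighbours of AT1 cells, were higher in the same libraries. Of 21 tested, 18 were higher, none was lower and 3 did not pass, and adjusted over the list alone 19 were higher. The surfactant protein gene Sftpc averaged 17988 FPKM in the libraries labelled Sox2 and 2900 FPKM in those labelled control, where single values were 5003 and 796 FPKM. The phosphate transporter Slc34a2 was 7.17-fold, the lung chemokine Cxcl15 7.17-fold, the lamellar body protein Lamp3 6.83-fold and the chitinase-like Chil1 6.66-fold higher. Leaving out labelled control replicate 1 gave 24.7, 29.4, 58.5 and 34.1, and leaving out labelled control replicate 2 gave 4.19, 4.08, 3.63 and 3.69. The median was 2.58 (camera adjusted p in limma 1.36e-19, adjusted p = 0.476 with an estimated correlation). It moved to 1.49 without labelled control replicate 2. Without labelled Sox2 replicate 2, Slc34a2 (adjusted p = 0.0551), Cxcl15 (0.0538), Lamp3 (0.0946), Chil1 (0.0918) and Sftpc (0.0788) missed limma's threshold. Without labelled Sox2 replicate 1, Cxcl15 (0.0774), Lamp3 (0.111), Chil1 (0.0675) and Sftpc (0.0754) missed it. Without labelled control replicate 2, Sftpc missed it as well (log2 difference 1.82, adjusted p = 0.420).

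Genes for ion and water transport were higher in the libraries labelled Sox2 or did not pass. Of 17 tested, 9 were higher in the libraries labelled Sox2, 8 did not pass and none was lower, with 10 higher and 1 lower adjusted over the list alone. Aqp5, the water channel of the AT1 cell surface, averaged 681 ± 248 FPKM (SD, n = 2) against 36.5 ± 5.54 FPKM (SD, n = 2). Aqp1 was 32.8-fold higher. The sodium channel subunits Scnn1b (16.6-fold) and Scnn1g (21.4-fold) were higher as well, as was Scnn1a (3.38-fold), whose promoter drives Cre here. The folds of Aqp1, Scnn1b and Scnn1g were 65.2, 46.0 and 77.8 without labelled control replicate 1, and 21.9, 10.2 and 12.4 without labelled control replicate 2. Scnn1a missed the threshold without labelled Sox2 replicate 2 (limma adjusted p = 0.0947). The median was 1.04 (camera adjusted p in limma 1.19e-09, adjusted p = 0.476 with an estimated correlation) and was 1.62 without labelled control replicate 1 and 1.81 with a filter at a mean of 5 FPKM.

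Basement membrane genes and vascular growth factors were higher in the libraries labelled Sox2 or did not pass. Of 19 tested basement membrane genes, 7 were higher, 12 did not pass and none was lower, with 11 higher adjusted over the list alone. Col4a4 was 18.0-fold higher, and the laminin chain Lama3 (6.67-fold) and Col4a2 (3.95-fold) passed with all libraries but not without labelled Sox2 replicate 2 (limma adjusted p = 0.0871 and 0.0767). These 3 folds were 48.7, 23.7 and 6.62 without labelled control replicate 1, and 11.0, 3.89 and 2.81 without labelled control replicate 2. The median was 1.28 (camera adjusted p in limma 2.06e-11, adjusted p = 0.476 with an estimated correlation) and 0.54 without labelled control replicate 2. Of 18 vascular growth factors and guidance cues, 8 were higher and 10 did not pass, with 9 higher and 1 lower adjusted over the list alone. Vegfa, the main growth factor for blood vessels, averaged 625 ± 9.64 FPKM (SD, n = 2) against 52.5 ± 23.6 FPKM (SD, n = 2), an 11.9-fold difference, and Sema3a was 26.3-fold higher (76.8 and 15.9 without labelled control replicate 1 or 2). The median was 0.96 (camera adjusted p in limma 1.23e-07, adjusted p = 0.476 with an estimated correlation), or 1.67 with a filter at a mean of 5 FPKM and 0.59 with no filter. Col4a4, Lama3, Vegfa and Sema3a are on the AT1 list too. Without genes shared between lists, the basement membrane median was 0.93 (camera adjusted p in limma 1.04e-07). That of the vascular list was then 0.79 (camera adjusted p in limma 2.05e-04).

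No club or ciliated cell marker passed the threshold in the direction of Sox2. Of 17 tested club cell markers, which belong to the secretory cells of the airway, 5 were higher in the libraries labelled Sox2, 12 did not pass and none was lower, with 10 higher adjusted over the list alone. The largest differences were those of Scnn1g and Scnn1b, which sit on the ion transport list too. The secretoglobin Scgb3a2 was 3.88-fold higher with all libraries but not past limma's threshold without labelled Sox2 replicate 2 (adjusted p = 0.114). Scgb1a1, the main club cell secretion, had a log2 difference of 1.28 (SE 0.41, limma adjusted p = 0.0629) and passed without labelled Sox2 replicate 1 (1.67, limma adjusted p = 0.0486), with a pseudocount of 0.1 (0.0496), with a filter at a mean of 5 FPKM (0.0407), under the robust variance model (0.00836) and without genes at several positions and small RNA genes (0.0432). The median was 1.21 (camera adjusted p in limma 6.42e-08, adjusted p = 0.476 with an estimated correlation) and 0.62 without labelled control replicate 2. Of 20 ciliated cell markers, 2 were higher and 18 did not pass, the same numbers as adjusted over the list alone. They were the lipid-binding Sec14l3 (7.54-fold) and the tubulin regulator Tppp3 (3.70-fold, limma adjusted p = 0.0686 without labelled Sox2 replicate 2). Their folds were 20.6 and 5.60 without labelled control replicate 1, and 4.61 and 2.77 without labelled control replicate 2. Foxj1, the regulator of motile cilia, stood at 13.1 ± 0.818 FPKM (SD, n = 2) in the libraries labelled Sox2 and 10.8 ± 1.65 FPKM (SD, n = 2) in those labelled control, and did not pass. The ciliated median was 0.31 (camera adjusted p in limma 8.34e-04, adjusted p = 0.537 with an estimated correlation). It was 0.07 without labelled Sox2 replicate 1, 0.59 without labelled Sox2 replicate 2, 0.83 without labelled control replicate 1 and -0.06 without labelled control replicate 2, and lay between 0.50 and 0.67 with a pseudocount of 0.1, a filter at a mean of 5 FPKM or either rescaling.

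Basal cell markers, genes of the stem cells of the airway, split in both directions. Of 13 tested, 7 were lower and 2 higher in the libraries labelled Sox2 and 4 did not pass, with the same counts adjusted over the list alone. Besides Dapl1, the lower members included the retinol dehydrogenase Adh7 at 0.0406 ± 0.00916 FPKM (SD, n = 2) against 38.6 ± 32.3 FPKM (SD, n = 2), and the integrin Itgb4 (19.0-fold lower, or 28.8 and 9.13 without labelled control replicate 1 or 2). Trp63, the regulator of basal cells, stood at 0.0605 and 0.0293 FPKM against 2.38 and 14.4 FPKM (limma adjusted p = 0.0145). Its call was lost under both rescalings (limma adjusted p = 0.0638 and 0.0744) and without labelled Sox2 replicate 1 (0.0779) or 2 (0.126). The keratins Krt5 and Krt14, which basal cells make in large amounts, did not exceed 0.686 and 0.101 FPKM in any library and were not tested. The higher members were Icam1 (log2 difference 3.06), an adhesion molecule, and Pdpn, a membrane protein that AT1 cells share. The list median was -1.40 (camera adjusted p in limma 0.0881, adjusted p = 0.517 with an estimated correlation), and the test passed without labelled Sox2 replicate 2 (median -1.03), labelled control replicate 1 (-1.85) or labelled control replicate 2 (-1.57). With no filter on low values the basal median was -0.56.

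Squamous and mucous genes were lower in the libraries labelled Sox2 or did not pass. Of 14 genes of stratified squamous keratinocytes, 5 were lower, 9 did not pass and none was higher, with 9 lower adjusted over the list alone. Krt4, a keratin of stratified linings, stood at 0.168 and 0.133 FPKM against 17.0 and 74.6 FPKM. Krt6a, a stress keratin, stood at 0 and 0.0312 FPKM against 3.23 and 78.9 FPKM, and its call was lost without labelled Sox2 replicate 1 (limma adjusted p = 0.0875) or 2 (0.139) and under both rescalings (0.0919 and 0.102). The median was -1.53 (camera adjusted p in limma 1.48e-04, adjusted p = 0.517 with an estimated correlation) and -0.53 without labelled control replicate 2, or -2.79 with a pseudocount of 0.1. Of 5 mucous cell markers, 3 were lower, 2 did not pass and none was higher, with 3 lower and 1 higher adjusted over the list alone. The airway mucin Muc5ac stood at 0.0463 and 0.0465 FPKM against 3.61 and 14.5 FPKM, and missed limma's threshold without labelled Sox2 replicate 2 (adjusted p = 0.0734). The mucous list had a median of -1.64 and did not pass (camera adjusted p in limma 0.110), but did without labelled control replicate 1 (median -1.96, adjusted p = 0.0185) or 2 (-1.28, 0.0356). That median was -2.72 with a pseudocount of 0.1, -0.10 with no filter and -0.61 with a filter at a mean of 5 FPKM. Of 18 neuroendocrine markers only 2 were expressed enough to be tested, Uchl1 (-1.23, limma adjusted p = 0.194) and Cplx2 (-0.30, 0.664), and that list did not pass either (median -0.76, camera adjusted p 0.592). Its median was -0.31 without labelled control replicate 1 and -1.22 without labelled control replicate 2. With no filter it was -0.03, with a filter at a mean of 5 FPKM -1.23, and under median-of-ratios rescaling -0.48.

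Genes of cell division were lower in the libraries labelled Sox2. Of 38 tested genes of mitosis and S phase, 27 were lower, 11 did not pass and none was higher, with 37 lower adjusted over the list alone. The mitotic kinase Aurkb averaged 3.87 ± 3.00 FPKM (SD, n = 2) against 40.1 ± 14.2 FPKM (SD, n = 2), and its partner Birc5 5.23 ± 2.40 FPKM (SD, n = 2) against 47.6 ± 10.3 FPKM (SD, n = 2). Mki67, the common marker of dividing cells, had a log2 difference of -1.87 (SE 0.44, limma adjusted p = 0.0214). It missed the threshold without labelled Sox2 replicate 1 (limma adjusted p = 0.0571), labelled Sox2 replicate 2 (0.209) or labelled control replicate 1 (0.0845). The median was -2.02 (camera adjusted p in limma 2.27e-14, adjusted p = 0.517 with an estimated correlation).

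Of 24 regulators of the G1 phase, 6 were lower, 1 was higher and 17 did not pass, with 12 lower and 1 higher adjusted over the list alone. Cyclin D1 (Ccnd1) averaged 22.2 ± 5.00 FPKM (SD, n = 2) against 143 ± 0.563 FPKM (SD, n = 2), and Mycl, a relative of the growth regulator Myc, was 16.7-fold lower (25.4 and 8.00 without labelled control replicate 1 or 2). Cdkn2a, whose products restrain the cell cycle, was 12.4-fold lower (23.7 without labelled Sox2 replicate 2), in the same direction as the cyclins. The higher member was the inhibitor Cdkn2b (1.22), which missed limma's threshold without labelled Sox2 replicate 1 (adjusted p = 0.0512), without labelled Sox2 replicate 2 (0.317) and without the variance trend (0.0620). The median was -1.01 (camera adjusted p in limma 0.00759, adjusted p = 0.517 with an estimated correlation), and the list did not pass with a filter at a mean of 5 FPKM (limma adjusted p = 0.0601). Of 13 p53 target genes, 6 were lower and 7 did not pass, with 6 lower adjusted over the list alone. Phlda3, a p53-induced inhibitor of Akt, was 7.20-fold lower, while the p53 target best known for arresting the cycle, Cdkn1a, had a log2 difference of -0.63 and did not pass. The p53 list had a median of -0.89 (camera adjusted p in limma 0.00759, adjusted p = 0.517 with an estimated correlation), or -0.58 under median-of-ratios rescaling.

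Transcription factors moved in both directions. Of 11 tested members of the SOX family other than Sox2, 3 were lower in the libraries labelled Sox2 and 8 did not pass, with 3 lower and 2 higher adjusted over the list alone. Sox21 averaged 0.321 ± 0.277 FPKM (SD, n = 2) against 59.0 ± 45.3 FPKM (SD, n = 2). Sox13 (-1.78) and Sox6 (-1.68) lost their calls without labelled Sox2 replicate 1 (limma adjusted p = 0.0506 and 0.108) or 2 (0.153 and 0.188). The family had a median of -0.25 and did not pass (camera adjusted p in limma 0.993). The median was 0.04 under median-of-ratios rescaling, -0.03 under quantile normalization, -1.12 with a filter at a mean of 5 FPKM and 0.06 without labelled control replicate 1. It was -0.41 without labelled Sox2 replicate 1, -0.09 without labelled Sox2 replicate 2 and -0.48 without labelled control replicate 2. Of 27 lung epithelial transcription factors, 4 were higher, 5 lower and 18 did not pass, with 8 higher and 7 lower adjusted over the list alone. Ehf, an epithelial ETS factor, was 15.5-fold lower (23.7 and 7.24 without labelled control replicate 1 or 2), and Grhl3, a regulator of skin barrier genes, was 13.8-fold lower. Etv5, an ETS factor of AT2 cells, was 4.04-fold higher (7.13 without labelled control replicate 1) but missed limma's threshold without labelled Sox2 replicate 1 (adjusted p = 0.0782) or 2 (0.0825). The list had a median of 0.30 but a mean of -0.01, with a camera adjusted p in limma of 0.0447 and an adjusted p = 0.476 with an estimated correlation. Its median was 0.64 under median-of-ratios rescaling and 0.63 under quantile normalization. Its call was lost under median-of-ratios rescaling (limma adjusted p = 0.0777), without labelled Sox2 replicate 2 (median 0.17, 0.181), without labelled control replicate 1 (0.688), with no filter (0.0751), without the variance trend (0.0594), without genes at several positions and small RNA genes (0.0547) and without genes shared between lists (median -0.09, 0.155).

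Epithelial junction and keratin genes were lower in the libraries labelled Sox2 in 7 of 22 tested, while 15 did not pass and none was higher; 11 were lower adjusted over the list alone. The tight junction protein Cldn4 averaged 37.2 ± 11.4 FPKM (SD, n = 2) against 186 ± 47.1 FPKM (SD, n = 2). Epcam, the general epithelial surface marker, was 3.63-fold lower but missed limma's threshold without labelled Sox2 replicate 2 (adjusted p = 0.0687). The median was -0.86 (camera adjusted p in limma 0.00759, adjusted p = 0.476 with an estimated correlation). The list's call was lost under median-of-ratios rescaling (median -0.52, limma adjusted p = 0.0593), quantile normalization (-0.55, 0.0523) and without labelled control replicate 2 (0.0890). Of 24 genes of xenobiotic metabolism, 5 were lower, 2 higher and 17 did not pass, with 6 lower and 2 higher adjusted over the list alone. Aldh3a1 was the largest, and the epoxide hydrolase Ephx1 was 11.7-fold lower (17.9 and 5.49 without labelled control replicate 1 or 2). That list did not pass (median -0.25, camera adjusted p in limma 0.581), and its median turned to 0.08 and 0.06 under the rescalings. It was -0.40 without labelled Sox2 replicate 1, and the list passed without labelled control replicate 1 (median -0.47, limma adjusted p = 3.27e-04). None of 18 cholesterol synthesis genes passed, also adjusted over the list alone (median -0.62, camera adjusted p in limma 0.167). Their median was -1.08 without labelled Sox2 replicate 1, -0.30 without labelled Sox2 replicate 2, -0.29 without labelled control replicate 1 and -0.96 without labelled control replicate 2, or -0.31 and -0.35 under the rescalings. The most abundant were Fdps, with a log2 difference of -0.60 (SE 0.36), and Hmgcs1, with -0.10 (SE 0.38), which turned to 0.24 and 0.22 under the rescalings.

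Among signalling genes, Wnt3a stood out at 16.5 ± 3.83 FPKM (SD, n = 2) in the libraries labelled Sox2 against 0.219 ± 0.109 FPKM (SD, n = 2). Of 21 tested Wnt pathway genes 3 were higher, 2 lower and 16 did not pass, with 3 in each direction adjusted over the list alone. The list had a median of 0.09 (camera adjusted p in limma 0.0339, adjusted p = 0.476 with an estimated correlation), and its call was lost without labelled Sox2 replicate 2 (limma adjusted p = 0.178), without labelled control replicate 1 (0.271) and with no filter on low values (0.0740). Its median was 0.05 without labelled Sox2 replicate 1 and 0.16 without labelled control replicate 2, or 0.19 with a filter at a mean of 5 FPKM, 0.37 under median-of-ratios rescaling and 0.32 under quantile normalization. Of 19 genes of BMP and TGF-beta signalling, 6 were higher, 2 lower and 11 did not pass, with 6 higher and 3 lower adjusted over the list alone. They included the BMP antagonist Noggin (Nog) at 16.8 ± 3.85 FPKM (SD, n = 2) against 1.46 ± 0.0611 FPKM (SD, n = 2) and the TGF-beta binding protein Ltbp3 (4.64-fold higher). The median was 0.71 (camera adjusted p in limma 5.77e-04, adjusted p = 0.476 with an estimated correlation), or 0.45 without labelled Sox2 replicate 1 and 0.46 without labelled control replicate 1, and 0.43 with no filter. None of 15 Notch pathway genes passed, also adjusted over the list alone (median 0.09, camera adjusted p in limma 0.172). Their median turned to -0.31 with a filter at a mean of 5 FPKM, and was 0.13 without labelled Sox2 replicate 2 and 0.14 without labelled control replicate 1, and 0.42 and 0.39 under the rescalings. The Notch target Hes1 averaged 76.6 ± 6.78 FPKM (SD, n = 2) against 74.0 ± 44.5 FPKM (SD, n = 2), and the ligand Jag2 had a log2 difference of -0.37 (SE 0.52). Without labelled control replicate 1 that of Hes1 was -0.46, and that of Jag2 was 0.22 without labelled Sox2 replicate 1 and 0.38 without labelled control replicate 2. Of 15 YAP and TAZ target genes, 2 were higher, 1 lower and 12 did not pass, the same as adjusted over the list alone. Ankrd1 (2.44) was among the higher and missed limma's threshold without labelled Sox2 replicate 1 (adjusted p = 0.0624). This list had a median of 0.20 (camera adjusted p in limma 0.0339, adjusted p = 0.517 with an estimated correlation), or 0.55 and 0.52 under the rescalings. It did not pass without labelled Sox2 replicate 2 (median 0.40, limma adjusted p = 0.0878), labelled control replicate 1 (0.76, 0.0596) or labelled control replicate 2 (0.04, 0.0757), nor with no filter (0.0988), a filter at a mean of 5 FPKM (0.0726) or without genes shared between lists (0.0705).

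**Figure D3:**
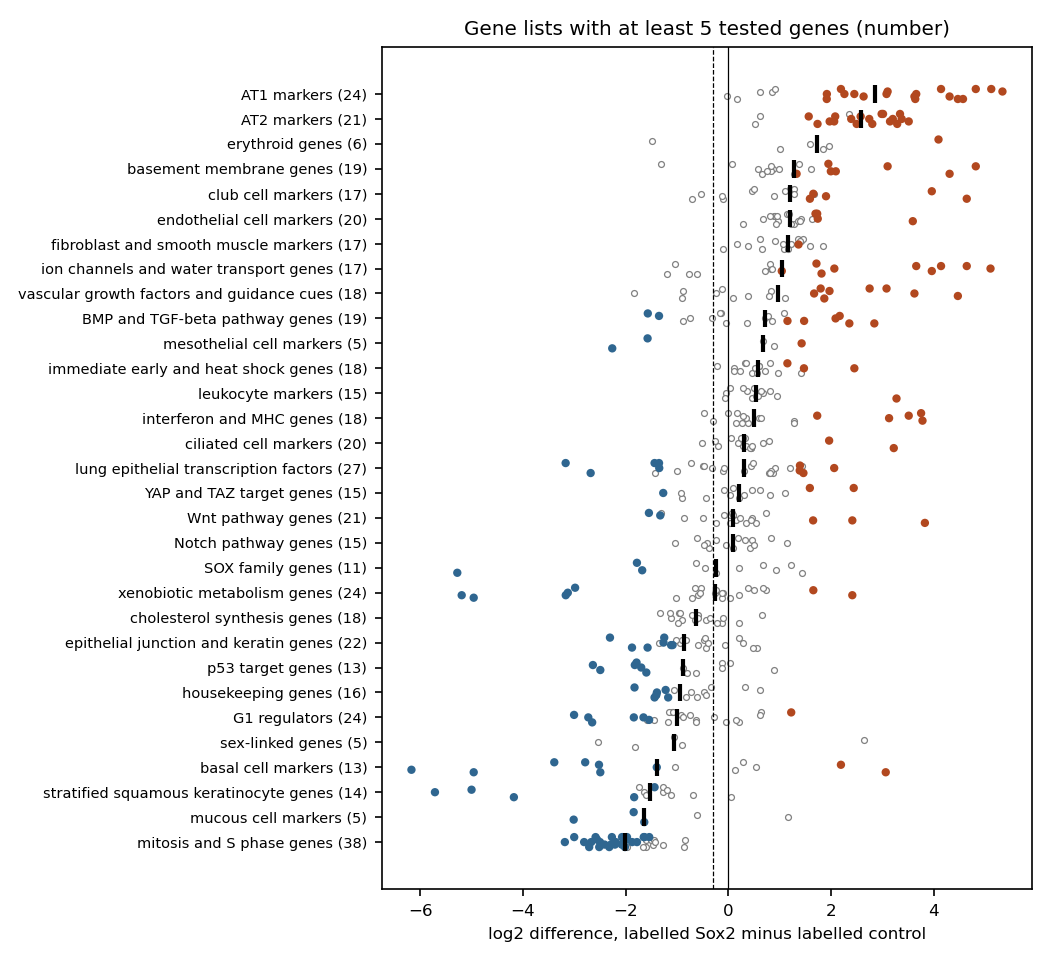
Log2 difference (labelled Sox2 minus labelled control, horizontal axis) of each tested member of the lists with at least 5 tested genes. Filled points passed the threshold, open points did not, black bars are list medians, and the dashed line is the median of all tested genes at -0.29. Medians run from -2.02 for mitosis and S phase genes to 2.86 for AT1 markers, and those of the SOX family and of xenobiotic metabolism change sign under median-of-ratios rescaling.

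Markers of other cell types that a lung sort can hold were measured in the same libraries. Of 20 endothelial markers, 4 were higher in the libraries labelled Sox2 and 16 did not pass, with 7 higher adjusted over the list alone. Esam, an adhesion molecule of vessels, was 12.6-fold higher (27.1 and 8.16 without labelled control replicate 1 or 2). Cdh5, the cadherin of endothelium, stood at 31.7 and 14.5 FPKM against 9.54 and 3.29 FPKM and lost its call without labelled Sox2 replicate 1 (limma adjusted p = 0.280), labelled Sox2 replicate 2 (0.104) or labelled control replicate 2 (0.112). The endothelial median was 1.20 (camera adjusted p in limma 6.73e-11, adjusted p = 0.517 with an estimated correlation), or 0.63 without labelled Sox2 replicate 1 and 0.74 without labelled control replicate 2. Of 17 fibroblast and smooth muscle markers only Eln, the elastin gene, was higher and 16 did not pass, with none past the threshold adjusted over the list alone. Eln was 2.47-fold higher and lost its call without labelled Sox2 replicate 1 (limma adjusted p = 0.135), labelled Sox2 replicate 2 (0.162) or labelled control replicate 2 (0.152). The median was 1.16 (camera adjusted p in limma 9.75e-07, adjusted p = 0.517 with an estimated correlation). It was 0.45 without labelled Sox2 replicate 1, 1.93 without labelled control replicate 1 and 0.34 without labelled control replicate 2. Of 15 leukocyte markers only Csf1r, the receptor of macrophage growth factor, was higher (13.1-fold, or 25.6 without labelled control replicate 1), also adjusted over the list alone, and 14 did not pass. The leukocyte median was 0.53 (camera adjusted p in limma 5.31e-04, adjusted p = 0.517 with an estimated correlation). It was -0.16 without labelled Sox2 replicate 1, where the test no longer passed (limma adjusted p = 0.103), 1.21 without labelled Sox2 replicate 2, 0.88 without labelled control replicate 1, 0.20 without labelled control replicate 2 and 0.81 under median-of-ratios rescaling.

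Most genes of the early stress response and most reference genes did not pass. Of 18 immediate early and heat shock genes, which can be induced by tissue digestion, 3 were higher in the libraries labelled Sox2 and 15 did not pass, the same as adjusted over the list alone. Fosb was 5.73-fold higher, and Nr4a1 (2.89-fold) lost its call without labelled Sox2 replicate 1 (limma adjusted p = 0.140). The median was 0.57 (camera adjusted p in limma 1.33e-06, adjusted p = 0.476 with an estimated correlation) and 0.91 without labelled Sox2 replicate 2, or 0.92 and 0.90 under the rescalings. Of 16 housekeeping genes, 6 were lower and 10 did not pass, with 8 lower adjusted over the list alone. Gapdh, an enzyme of glycolysis, averaged 268 ± 44.8 FPKM (SD, n = 2) against 957 ± 189 FPKM (SD, n = 2) and missed limma's threshold without labelled Sox2 replicate 2 (adjusted p = 0.0716). The median was -0.94 (camera adjusted p in limma 0.00852, adjusted p = 0.622 with an estimated correlation), or -0.61 under either rescaling, and the list's call was lost without labelled control replicate 1 (limma adjusted p = 0.0982).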

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

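The settings without genes at several positions and small RNA genes, and without genes shared between lists, were chosen after seeing the data, and the others before. Sox2 stayed lower in the libraries labelled Sox2 and past the threshold in every setting run. Against 506 higher and 976 lower genes, no filter on low values gave 0 and 3 in limma (1251 and 2618 at an unadjusted p under 0.05), median-of-ratios rescaling 964 and 686, and quantile normalization 980 and 827. Leaving out 1 library gave 119 to 837 higher and 115 to 1312 lower genes. The replicate number as a block gave 1142 and 2730. Same-numbered libraries deviated together (r = 0.234 across genes, or 0.314 without small RNA genes). Median differences of replicate 1 minus 2 were alike in both labels for some lists, such as endothelial markers (labelled control 0.90, labelled Sox2 1.08). For others they were not, such as AT1 markers (1.25 and -0.17) and squamous genes (-1.84 and 0.02). The main test left such shared deviations in the spread. The labels call the animals littermates. With 2 pairs and no label that ties a number to a litter, the numbers were not taken as pairs. The remaining settings stayed within 1.5 times of both counts, and every gene called both there or in any other setting and in the main test kept its direction. All 23 list calls were lost when camera used an estimated correlation. The directional fry test passed none of these lists. It asks whether a list's genes changed on balance in a common direction, and not whether they changed more than other genes. Of the 23 calls, 20 were kept under median-of-ratios rescaling, 21 under quantile normalization and 23 with the replicate block. Medians were 2.86 for AT1 (adjusted p = 0.476 and, for fry, 0.170), 2.58 for AT2 (0.476 and 0.249), 1.21 for club (0.476 and 0.170), 0.31 for ciliated (0.537 and 0.524) and -2.02 for mitosis and S phase (0.517 and 0.249). The basal list passed in 3 of 4 fits with 1 library left out, with medians from -1.85 to -1.03 in these. Some genes that did not pass changed sign. Hes1 ranged from -0.46 to 0.83 and Jag2 from -1.13 to 0.38 with 1 library left out, and Hmgcs1 from -0.53 to 0.33 (0.24 under median-of-ratios, 0.22 under quantile normalization). Beyond what the construction of a setting shows (fewer libraries, other genes tested), the cause was not tested. With 1 library left in a label, its spread was assumed to equal that of the other label. Without Cuffdiff p-values tied to the groups, the planned comparison with the authors' calls was not run.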

Other observations

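The tests of explanations in this part were chosen after the results were seen, the gene lists before, and directions follow the labels, against which Sox2 runs. Genes of antigen presentation were higher in the libraries labelled Sox2 or did not pass. Of 18 interferon and MHC genes, 5 were higher in the libraries labelled Sox2 and 13 did not pass, with 7 higher adjusted over the list alone. The members of MHC class II led: H2-Aa averaged 81.9 ± 24.3 FPKM (SD, n = 2) against 5.27 ± 3.00 FPKM (SD, n = 2), and Cd74, which chaperones class II molecules, was 11.8-fold higher (27.0 and 7.55 without labelled control replicate 1 or 2). H2-Ab1 (3.51) and H2-Eb1 (3.13) had log2 differences of similar size, and these 4 calls held with any 1 library left out. The list median was 0.49 (camera adjusted p in limma 1.25e-07, adjusted p = 0.476 with an estimated correlation), or 0.79 and 0.74 under the rescalings. Macrophages and AT2 cells are known to make class II molecules. In the same libraries 18 of 21 AT2 markers were higher. Of 15 leukocyte markers the macrophage receptor Csf1r was higher (13.1-fold, or 25.6 without labelled control replicate 1) and 14 did not pass, and the leukocyte median of 0.53 turned to -0.16 without labelled Sox2 replicate 1. The source of the class II transcripts stays open.

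Erythroid, mesothelial and sex-linked genes differed between libraries of the same label. Of 6 erythroid genes Hba-a2 was higher in the libraries labelled Sox2 and 5 did not pass, with 3 higher adjusted over the list alone, though globin genes have near-identical copies and are uncertain. Their median was 1.72 (camera adjusted p in limma 0.00311, adjusted p = 0.517 with an estimated correlation), and the call was lost without labelled Sox2 replicate 2 (limma adjusted p = 0.153), without labelled control replicate 1 (0.271) and under both rescalings (0.116 and 0.104) and without genes at several positions and small RNA genes (0.0521). The median was 2.86 without labelled Sox2 replicate 1, 0.58 without labelled Sox2 replicate 2, 0.72 without labelled control replicate 1 and 2.75 without labelled control replicate 2, or 0.74 with no filter. Hba-a2 itself missed limma's threshold without labelled Sox2 replicate 2 (adjusted p = 0.170), under median-of-ratios rescaling (0.0645), under quantile normalization (0.0675), under the robust variance model (0.340) and with no filter on low values. Replicate 1 minus replicate 2 gave an erythroid median of -1.78 log2 units for the libraries labelled Sox2 and -2.08 for those labelled control. The same difference for fibroblast and smooth muscle markers was 1.44 and 1.58. Of 5 mesothelial markers Gpm6a was higher, Aldh1a2 and Krt19 were lower and 2 did not pass, with 2 in each direction adjusted over the list alone. These 3 calls were lost without labelled Sox2 replicate 2 (limma adjusted p = 0.121, 0.170 and 0.0716), and the list did not pass (median 0.67, mean -0.17, camera adjusted p 0.619). Krt19 lost its call under both rescalings too, and Gpm6a with a pseudocount of 0.1. The mesothelial median turned to -0.26 without labelled Sox2 replicate 1, -0.19 without labelled control replicate 2 and -0.34 with a filter at a mean of 5 FPKM. Xist, which marks cells with 2 X chromosomes, stood at 41.1 FPKM in labelled Sox2 replicate 1 and at most at 0.156 FPKM elsewhere. The Y-linked Eif2s3y stood at 0.0375 FPKM in that library and at 15.5, 26.4 and 20.4 FPKM in the others. None of the 5 sex-linked genes passed, and their list passed only without labelled Sox2 replicate 2 (median -1.88, limma adjusted p = 0.0105, against -1.06 and 0.557 with all libraries). Their median was -0.06 without labelled Sox2 replicate 1, -2.55 with a pseudocount of 0.1 and -1.82 with a filter at a mean of 5 FPKM.

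The Sox2 transcript was abundant in the libraries that should lack the transgene by their label. Airway secretory and ciliated cells carried into the libraries labelled control would bring their markers, but the median log2 difference of 37 club and ciliated markers was 0.449 (lower quartile 0.219), on the other side. Basal cells would bring Krt5, which reached at most 0.047 of the Trp63 level in a library labelled control, and basal cells hold far more of it. An exchange of the labels or of the files between the groups is a candidate explanation. The lowest library labelled control held 152 times the Sox2 level of the highest library labelled Sox2, but this restates the pattern, and no transcript of the control reporter is among the tested genes to decide. Another source of Sox2 in the libraries labelled control covers only that side of the pattern. The libraries whose label carries the transgene held only 1.41 and 1.99 FPKM, which argues against another source as the only explanation. An exchange would account for both sides. No value here tests an exchange directly, and under it every direction given would turn.

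AT2 markers were higher in the libraries labelled Sox2, in cells sorted as AT1 cells. Scaling between libraries is argued against, since the smaller list median under both rescalings was 2.91, against 2.58 as deposited. AT2 cells carried over in differing shares would shift all AT2 markers by a common factor only if the sorted cells made none of them, which was not tested. In that case their log2 differences would lie close together. The interquartile range of these differences, 1.088, stood at percentile 50.2 among 10000 random lists matched on expression (median 1.085). Resampling the 21 members gave 0.599 to 1.638, an interval added after that percentile was seen. The spread of random lists does not show what spread carry-over would leave. This test therefore cannot tell carry-over from a change within the sorted cells. Between the libraries labelled control, all 21 AT2 markers were higher in replicate 1 than in replicate 2. The median was 2.04 log2 units, or 1.71 after median-of-ratios rescaling, so the list also shifted between libraries of the same label. A difference between the genotypes stays open as a biological explanation and was not tested.

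Squamous genes were lower in labelled control replicate 1 than in replicate 2, with a median difference of -1.84 log2 units for 14 genes, 0 of them higher in replicate 1. Scaling is argued against, since the median was -1.98 (upper quartile -1.526) after median-of-ratios rescaling. Cells like those of the libraries labelled Sox2, mixed into replicate 1, would raise AT1 and AT2 markers there. These markers were higher there, with a median of 1.25 for AT1, 2.04 for AT2 and 1.545 for all 45 markers (lower quartile 0.933). Mixing would also lower the genes found almost only in the libraries labelled control. Of 91 such genes, 38 were higher in replicate 1 (median -0.37, quartiles -1.233 and 0.936). They were chosen as called lower in the libraries labelled Sox2 by at least 2 log2 units, with a mean under 1 FPKM there. A call favours genes on which the 2 libraries labelled control are close, so this count cannot speak against mixing. With 2 single libraries, mixing and other differences between them cannot be told apart. Mitosis and S phase genes were higher in replicate 1 by similar medians in both labels (1.08 for labelled control and 1.14 for labelled Sox2, as deposited). Median-of-ratios rescaling lowered the medians within labelled control to 0.93 for AT1, 1.71 for AT2 and 0.75 for mitosis and S phase. Age, day 3 or 4 per the labels, stays open as an untested biological difference.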
